A study of Mus musculus with 28 samples.

How the data were processed

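RNA was measured in 28 libraries of 100 sorted cells each, from 9 populations of mouse embryos at 3 embryonic days. Cells were sorted directly into lysis buffer and libraries were made with a SMARTer Ultra Low Input kit, per the labels' protocols. The deposited values are raw counts per gene symbol, with mm9 gene coordinates beside them. The tools TopHat, SAMtools, Subread and featureCounts 1.6.2 and the genome build mm9 are named in the submitters' processing notes, and the column layout is that of featureCounts per the file headers. Strand setting, treatment of reads with several matches and the annotation release are not given in the sources used here. Reads from near-identical copies (Lyz1 and Lyz2, Ifitm genes, hemoglobins, H2-K1 and H2-D1, ribosomal proteins) and from overlapping genes can therefore be split in unknown ways, and their values are uncertain. The sort gates are also not given in the sources used here.

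Each count column was matched to a library by its name, and groups and replicate numbers were taken from the labels. The table held 24015 genes, of which 2723 were at 0 in all libraries. Totals per library ran from 16308918 to 31405603 counts, and after scaling 3 counts correspond to 0.188 CPM in the library of smallest scaled size (E8.5 EC replicate 3) and 0.108 CPM in that of the largest (E10.5 HE replicate 1). Intervals and floors cover counting error only, since amplified reads are not independent molecules. Replicates of a group correlated at 0.907 to 0.956 (log2 CPM, across genes, which are not independent replicates), and no pair matched within sampling noise (chi-square per degree of freedom of 38.5 or more). Nothing in the labels says that replicates came from separate litters or embryos, so p-values measure only the spread between these samples, which may be technical.

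The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 15238 genes. Libraries were scaled by TMM factors, and a quasi-likelihood model with 1 coefficient per population was fitted to all 28 libraries, so that all comparisons share 1 estimate of the spread (common biological coefficient of variation 0.563). The 6 comparisons within a day, the 5 between days and the 4 differences of differences were contrasts of this model, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Means and SDs in CPM use the same scaling. Where a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group. Where it had 1 to 3 counts, the depth-scaled ratio of the summed counts is given with its 95% counting interval.

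Named genes were the 8 largest rises and the 8 largest falls in each comparison within a day and the 5 and 5 in each comparison between days, among called genes with a mean of at least 10 CPM in the higher group and no overlap between libraries. Unnamed gene models, microRNAs, small nucleolar RNAs and pseudogenes were left out. No overlap arises by chance in 10% of genes for 3 libraries against 3. For each difference of differences the 5 smallest p were taken, with a mean of at least 10 CPM in 1 of the groups. A fixed panel of 20 genes, up to 4 members with the smallest p of each list described, and the surface markers used as checks were added. Not all genes under this rule are described.

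The 22 gene lists and 12 marker lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 34 lists of a comparison. Of the 226 list calls, 95 also hold with an estimated correlation, and those that do not have that p beside them. Members were counted as called among all genes and also adjusted over the list alone. Levels of lists are means of log2(CPM + 1). Overlaps between comparisons used Fisher's exact test, one-sided, as a description, since genes are not independent replicates. No library was shared between the comparisons paired, but the estimate of spread was.

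The model was tested on simulated data with 200 genes changed by known folds. The changed genes had at least 10 CPM, and the spread of a gene depended only on its level. Libraries with the same replicate number shared no deviation in the simulated data. The shares recovered and the false calls may therefore differ in the real data. For E9.5 HE against EC edgeR recovered 21.2% of genes changed 2-fold, 94.0% of those changed 4-fold and 100% of those changed 8-fold among 14785 genes, with 2 false calls of 146. For E8.5 HE against EC the shares were 30.3%, 91.0% and 97.0% among 14786 genes, with 7 false calls of 153. For pre-HSC II against pre-HSC I they were 28.8%, 89.6% and 97.0% among 14797 genes, with 11 false calls of 155.

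Alternatives were DESeq2 1.42.0, limma voom with quality weights, DESeq2 size factors or upper-quartile factors in edgeR, no filter, a stricter filter of 10 CPM in 3 libraries, a fold minimum of 2, only the groups compared in the fit, removal of hemoglobin genes, the replicate number as a block and leaving out each library in turn. For the lists they were an estimated correlation and fry. The run without 3 libraries rich in hemoglobin reads was added after seeing the data. A further test of the source of these hemoglobin reads, also chosen after seeing the data, is not reported here. Libraries with the same replicate number deviated together from their group means in the comparisons of HE with EC at E8.5 (correlation 0.193 to 0.240), E9.5 (0.198 to 0.472) and E10.5 (0.167 to 0.383), of pro-HSC/HPC with HE (0.204 to 0.532) and of pre-HSC I with HE (0.172 to 0.410). All of these exceed 0.1, so the numbers were taken as pairs there, from the data and not from the labels, and the blocked count stands beside each result it moves by more than 1.5 times. At E8.5 the pairs are less clear, since EC replicate 3 correlated as well with HE replicate 4 (0.200) as with HE replicate 3 (0.198). HE replicate 4 has no EC library of its number, so the block takes it out of the E8.5 contrast.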

Results

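RNA sequencing counts were analysed for 28 libraries, each made from 100 sorted cells of mouse embryos that carried the transgene labelled 23GFP. The labels place them in 9 populations over 3 embryonic days. At E8.5 these were endothelial cells (EC, 3 libraries) and hemogenic endothelium (HE, 4 libraries), the endothelium from which blood cells arise. At E9.5 they were EC, HE and a population labelled pro-HSC/HPC, where HPC stands for hematopoietic progenitor cell. At E10.5 they were EC, HE, pre-HSC I and pre-HSC II, with 3 libraries in each E9.5 and E10.5 population. The tissue is labelled PAS+VU at E8.5 and E9.5 and AGM+VU at E10.5, terms that the labels leave unexpanded. Totals ran from 16308918 counts, in an E10.5 EC library, to 31405603 counts, in an E8.5 EC library. In each library 13935 to 16050 genes had at least 1 count.

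Cdh5, the endothelial cadherin, was detected in all populations. Its mean was 105 ± 20.6 CPM (counts scaled to a common library size) in E8.5 EC, 329 ± 139.8 in E8.5 HE, 785 ± 199 in E9.5 HE, 719 ± 21.6 in E10.5 HE and 77.2 ± 14.2 in pre-HSC II (SD, with the library numbers given above here and throughout). Runx1, a transcription factor required for blood formation, averaged between 2.17 and 3.61 CPM in the EC populations and in E8.5 HE. It averaged 35.0 ± 3.67 CPM in E9.5 HE, 45.0 ± 6.61 in E10.5 HE, 254 ± 25.1 in pro-HSC/HPC, 225 ± 50.9 in pre-HSC I and 249 ± 59.5 in pre-HSC II. Ptprc, which encodes CD45, averaged 0.939 ± 0.272 CPM in pro-HSC/HPC, 11.4 ± 5.06 in pre-HSC I and 100.0 ± 34.4 in pre-HSC II, and at most 0.707 in the EC and HE populations. Spn, which encodes CD43, averaged 9.75 ± 3.78 CPM in pro-HSC/HPC, 38.9 ± 11.7 in pre-HSC I and 52.7 ± 7.03 in pre-HSC II. Itga2b, which encodes CD41, averaged 29.7 ± 8.03 CPM in E8.5 HE, 3.87 ± 0.769 in E10.5 HE and 28.8 ± 13.9 in pre-HSC I. Kit, a receptor of blood progenitors, averaged 50.9 ± 13.6 CPM in E10.5 HE and 309 ± 77.7 in pre-HSC II.

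**Figure D1:**
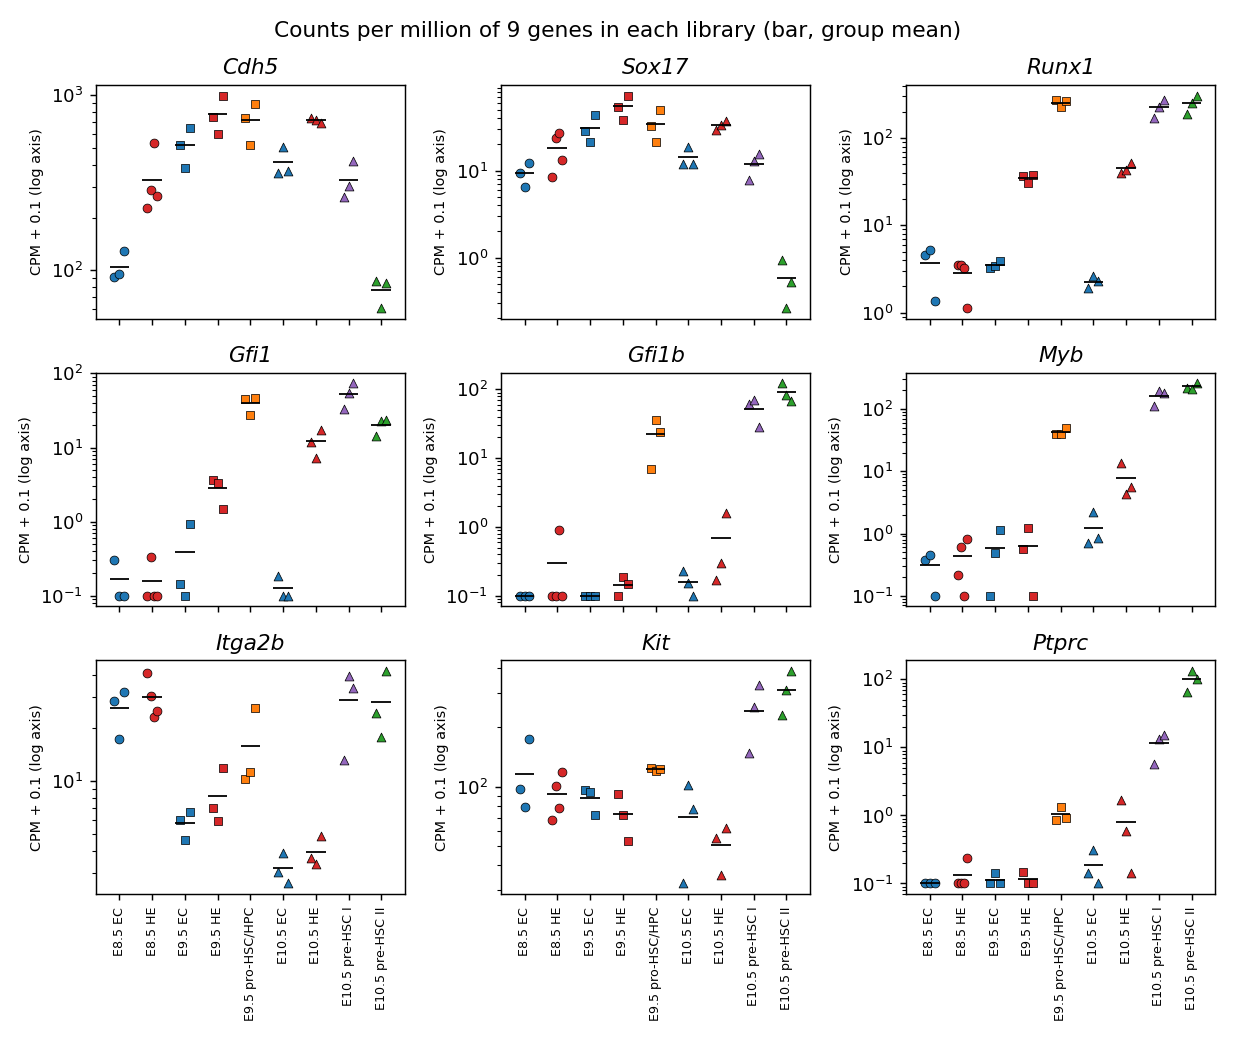
CPM plus 0.1 of 9 genes on logarithmic vertical axes, with 1 point per library and a bar at each group's mean, for the 9 populations on the horizontal axis. Runx1 averaged 2.17 CPM in E10.5 EC, 45.0 in E10.5 HE and 225 in pre-HSC I.

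Markers of other cell types differed between the populations. The erythroid list, whose level is the mean log2(CPM + 1) over its members, averaged 3.70 in pro-HSC/HPC and 2.57 in pre-HSC I, against 1.13 to 1.56 in the EC and HE populations. Embryonic hemoglobin transcripts made up 1.11% and 0.422% of the counts in pro-HSC/HPC replicates 2 and 3 and 0.172% in pre-HSC I replicate 3. The megakaryocyte and platelet list averaged 3.91 in pro-HSC/HPC and 3.23 in pre-HSC II. Granulocyte and macrophage genes averaged 1.83 in pro-HSC/HPC, 2.56 in pre-HSC I and 3.63 in pre-HSC II. The mast cell list, with 3 genes tested, averaged 0.121 in E8.5 EC and 3.05 in pre-HSC II. Mesenchyme and smooth muscle genes averaged 3.23 in E10.5 HE and 1.30 in pre-HSC II. Cardiac genes averaged 2.83 in pro-HSC/HPC and 1.13 in pre-HSC II, and mesonephros and intermediate mesoderm genes averaged 2.53 in E10.5 HE. Germ cell genes averaged at most 0.828 and endoderm and epithelium genes at most 1.11 in any population.

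**Figure D2:**
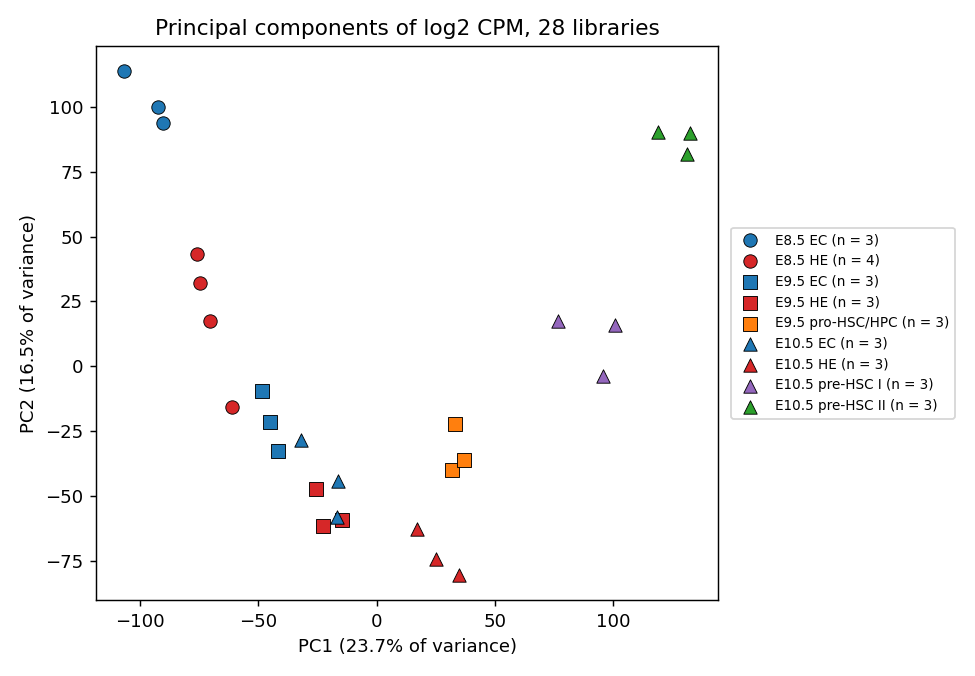
Principal component scores of the 28 libraries from log2 CPM, with the first component (23.7% of the variance) on the horizontal axis and the second (16.5%) on the vertical axis. Each point is 1 library of the 9 populations, and the first component runs from E8.5 EC replicate 3 at -106.55 to pre-HSC II replicate 2 at 132.32.

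HE was compared with EC of the same day to ask how the population that gives rise to blood differs from other endothelium. At E8.5 HE had higher levels of many vascular genes than EC, while Runx1 did not differ by the test. Esm1, a secreted proteoglycan of endothelial tip cells (chromosome 13, 113999867 to 114008312, mm9), averaged 59.5 ± 42.7 CPM in HE and 0.0608 ± 0.0207 in EC (log2 difference 9.82 ± 1.32 SE, edgeR adjusted p = 2.9e-05). Cd109, a membrane glycoprotein (chromosome 9, 78463353 to 78564067), rose by 8.75 ± 0.57 on the log2 scale, the arterial connexin Gja5 by 8.29 ± 0.85 and the adaptor Nedd9 by 7.63 ± 0.69. Prss23, a serine protease, had 927 counts over the HE libraries and 1 over the EC libraries, a depth-scaled ratio of 645 (95% counting interval 116 to 25518). Mecom, a transcription factor of stem cells and arterial endothelium, averaged 94.0 ± 42.5 CPM in HE and 8.03 ± 4.23 in EC (log2 3.56 ± 0.40, edgeR adjusted p = 1.6e-06). Lower in HE were Dkk1, a Wnt inhibitor, with 1.14 ± 0.567 CPM against 14.4 ± 1.98 (log2 -3.66 ± 0.66, edgeR adjusted p = 0.00081), and the homeobox genes Hoxa7 (log2 -2.30 ± 0.45) and Hoxa9 (log2 -2.08 ± 0.41). Hlf, a stem cell transcription factor, had 0 counts in the HE libraries and was at least 54.6-fold lower there than in EC, against a floor of 3 counts over the group. Runx1 averaged 2.76 ± 1.16 CPM in HE and 3.61 ± 2.07 in EC (log2 -0.41 ± 0.34, edgeR adjusted p = 0.53).

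Endothelial identity genes were higher in E8.5 HE as a group, and 14 of 25 rose (14 adjusted over the list alone), with Emcn at log2 3.04, Clec14a at 2.80 and Cdh5 at 1.65 (camera adjusted p = 1.1e-09). Among genes of flow response and vascular tone 9 of 16 rose (11 adjusted over the list alone), including the phosphodiesterase Pde2a at log2 3.99 and the potassium channel Kcnj2 at 5.88 (camera adjusted p = 4.4e-13). Of 20 arterial genes 10 rose and 1 fell (12 and 1 adjusted over the list alone), with the ephrin Efnb2 at log2 2.98 and the Notch ligand Jag1 at -1.53 (camera adjusted p = 3.8e-08, and adjusted p = 0.14 with an estimated correlation). Ribosome biogenesis and MYC genes were lower, and 16 of 26 fell (22 adjusted over the list alone, where 1 rose), including the nucleolar genes Nolc1 at log2 -1.14 and Wdr12 at -1.12 (camera adjusted p = 1.0e-15). In the Hox list 4 of 31 fell and 1 rose (7 and 1 adjusted over the list alone), with Hoxa10 at log2 -2.01 (camera adjusted p = 0.0041, and adjusted p = 0.14 with an estimated correlation). Marker lists of other cells stood apart as well. The mast cell list, with only 3 genes tested, ran from 0.0292 to 0.186 in the EC and 0.496 to 0.858 in the HE libraries (camera adjusted p = 0.049, and adjusted p = 0.14 with an estimated correlation). The mesonephros and intermediate mesoderm list ran from 0.993 to 1.68 and 1.90 to 2.28 (camera adjusted p = 0.14). Car2, a carbonic anhydrase, ran from 39.0 to 42.0 CPM in EC and 198 to 371 in HE. In all edgeR called 1038 of 15238 genes, 774 higher and 264 lower in HE. In each run that left out 1 library 17 of the 22 called genes from the size rule and the panel kept their call, as did 45 of 64 further called genes from the lists. The count was 2193 with the replicate number as a block, 191 when only the E8.5 libraries entered the fit and 582 without E8.5 HE replicate 3.

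At E9.5 Runx1, Cd44 and arterial genes were higher in HE than in EC. Runx1 (chromosome 16, 92601711 to 92826319) averaged 35.0 ± 3.67 CPM in HE and 3.42 ± 0.323 in EC (log2 3.36 ± 0.38, edgeR adjusted p = 3.5e-05). Cd44, an adhesion receptor, averaged 117 ± 14.5 and 20.4 ± 5.77 CPM (log2 2.52 ± 0.31, edgeR adjusted p = 0.00011). Akr1c14, an aldo-keto reductase (chromosome 13, 4058837 to 4089668), rose by 6.71 on the log2 scale. Vwf, the von Willebrand factor of endothelium and platelets, rose by 3.19 ± 0.50. Tmem100, an endothelial membrane protein, averaged 328 ± 94.6 CPM in HE and 31.8 ± 4.97 in EC, and Gja5 averaged 170.0 ± 39.3 and 16.7 ± 10.3 CPM. Gfi1, a transcriptional repressor of blood cells, averaged 2.71 ± 1.17 CPM in HE and 0.291 ± 0.468 in EC and did not pass the test (edgeR adjusted p = 0.16), and neither did Sox17 (log2 0.82 ± 0.44) or Cdh5 (log2 0.60 ± 0.29).

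Of 20 arterial genes 5 rose (16 adjusted over the list alone), with the connexin Gja4 at log2 2.72 and the growth factor Vegfc at 2.82 (camera adjusted p = 3.2e-37). Hematopoietic transcription factors were higher as a group, with 2 of 22 called (6 adjusted over the list alone), Runx1 and Ikzf2 at log2 1.96 (camera adjusted p = 3.1e-08). In the pan-hematopoietic list 1 of 27 rose, Cd44 (5 adjusted over the list alone, camera adjusted p = 5.3e-07). In the stem cell list 1 of 22 rose, the cell cycle inhibitor Cdkn1c at log2 1.35 (6 adjusted over the list alone, camera adjusted p = 5.8e-08). Among marker lists of other cells, mesonephros and intermediate mesoderm genes were higher in HE with 1 of 7 called (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.023). The higher genes were Ret at log2 3.39 and Gata3 at 1.43. The lower gene was Wt1, with 0 counts in HE and 1.76 ± 3.00 CPM in EC, and Pax8 also had 0 counts in HE. Whether cells of that type were present in the HE libraries was not tested. EC replicate 3 stood apart at 4.04 in the mesenchyme and smooth muscle list and 1.89 in the neural and neural crest list, against 1.84 and 1.97, and 1.03 and 0.817, in EC replicates 1 and 2. edgeR called 46 genes, each higher in HE. The 0 lower calls stood beside 368 genes lower at an unadjusted p under 0.05, and DESeq2 called 12 and limma voom 38 lower. The count was 168 with the replicate block, 140 with only these libraries in the fit, 19 without EC replicate 1, 11 without EC replicate 2 and 29 without HE replicate 1. Of the 9 called genes from the size rule and the panel 4 kept their call in each such run, Akr1c14, Cd44, Runx1 and Vwf. So did 2 of 9 further called genes from the lists.

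At E10.5 HE had higher levels of blood transcription factors and arterial genes than EC and lower levels of venous genes. Runx1 averaged 45.0 ± 6.61 CPM in HE and 2.17 ± 0.351 in EC (log2 4.37 ± 0.40, edgeR adjusted p = 3.0e-07). Gata2, a transcription factor of blood stem cells and endothelium, averaged 213 ± 25.8 and 71.7 ± 13.7 CPM (log2 1.57 ± 0.21, edgeR adjusted p = 4.8e-05). Gfi1 (chromosome 5, 108145674 to 108154825) had 863 counts over the HE libraries and 2 over the EC libraries, a depth-scaled ratio of 379 (95% counting interval 105 to 3137). Cd44 averaged 231 ± 36.5 CPM in HE and 22.1 ± 2.22 in EC (log2 3.38 ± 0.32), and Nupr1, a stress-induced chromatin protein, rose by 7.77 ± 0.72 on the log2 scale. Spry1, an inhibitor of growth factor signalling, averaged 1.54 ± 0.921 CPM in HE and 21.0 ± 4.01 in EC (log2 -3.75 ± 0.46, edgeR adjusted p = 1.5e-05). Cdh5 (log2 0.80 ± 0.29, edgeR adjusted p = 0.15) and Kit (log2 -0.47 ± 0.35, edgeR adjusted p = 0.58) did not pass the test.

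Of 20 arterial genes 12 rose (19 adjusted over the list alone), with Gja4 at log2 3.30 and Jag1 at 2.58 (camera adjusted p = 2.8e-28). Venous and lymphatic genes were lower, and 4 of 10 fell (5 adjusted over the list alone), with the apelin receptor Aplnr at log2 -3.61 and the venous transcription factor Nr2f2 at -3.02 (camera adjusted p = 4.1e-09). Hematopoietic transcription factors rose in 8 of 22 cases (10 adjusted over the list alone, camera adjusted p = 7.1e-15), among them Ikzf2 at log2 3.68. Stem cell genes rose in 9 of 22 (12 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.7e-12), among them the receptor Gpr56 at log2 3.23. S phase genes were lower as a group with 3 of 26 called (12 adjusted over the list alone), including the replication helicase genes Mcm5 at log2 -0.85 and Mcm3 at -0.62 (camera adjusted p = 9.8e-12). So were ribosome biogenesis and MYC genes with 6 of 26 (16 adjusted over the list alone, camera adjusted p = 3.1e-12). In the interferon and inflammatory list 5 of 34 rose (8 adjusted over the list alone), with Stat3 at log2 1.11, and with Ifitm3 at 1.79, whose reads are uncertain because Ifitm genes are near copies (camera adjusted p = 7.2e-05). The mesenchyme and smooth muscle list stood at 3.23 in E10.5 HE and 2.30 in E10.5 EC. edgeR called 530 genes, 321 higher and 209 lower. Of the 25 called genes from the size rule and the panel, 11 kept their call in each run that left out 1 library, as did 35 of 59 further called genes from the lists. The count was 1316 with the replicate block, 285 and 284 without EC replicates 1 and 3 in turn, and 314 and 302 without HE replicates 2 and 3.

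The blood populations were set against HE of their day to follow the step from endothelium to blood. In pro-HSC/HPC the blood transcription factors were far above HE while Cdh5 was measured at a like level. Runx1 averaged 254 ± 25.1 CPM in pro-HSC/HPC and 35.0 ± 3.67 in HE (log2 2.86 ± 0.36, edgeR adjusted p = 5.2e-05). Myb, a transcription factor of progenitors (chromosome 10, 20844736 to 20880790), averaged 43.0 ± 6.15 and 0.536 ± 0.570 CPM (log2 6.29 ± 0.86, edgeR adjusted p = 0.00011). Gfi1b, a repressor of the Gfi1 family, had 3 counts over the HE libraries and a depth-scaled ratio of 473 (95% counting interval 162 to 2297). Rgs18, a regulator of G protein signalling in platelets, had 0 counts in HE and was at least 395-fold higher in pro-HSC/HPC, and the platelet chemokine Pf4 rose by 7.94 ± 1.27 on the log2 scale. Nr2f2 fell by 4.02 on the log2 scale, from 216 ± 39.1 to 13.4 ± 1.62 CPM (edgeR adjusted p = 0.0056), and the cyclin Ccnd1 changed by -2.42 ± 0.32. Cdh5 averaged 719 ± 189 CPM in pro-HSC/HPC and 785 ± 199 in HE (log2 -0.13 ± 0.29, edgeR adjusted p = 1).

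Hematopoietic transcription factors rose in 8 of 22 cases (13 adjusted over the list alone, camera adjusted p = 1.6e-24). Of 27 pan-hematopoietic genes 7 rose (13 higher and 1 lower adjusted over the list alone), with the platelet and leukocyte gene Plek at log2 5.68 (camera adjusted p = 2.0e-21). Stem cell genes rose in 4 of 22 cases (11 adjusted over the list alone), with Gpr56 at log2 3.69 and the angiopoietin Angpt1 at 3.56 (camera adjusted p = 7.1e-14). Venous and lymphatic genes fell in 3 of 10 cases (6 adjusted over the list alone), with Flt4, a receptor of lymphatic vessels, at log2 -1.73 (camera adjusted p = 4.2e-15). Marker lists of mature blood cells were also higher by the test, with 3 of 16 megakaryocyte and platelet genes (12 adjusted over the list alone, camera adjusted p = 1.2e-15), including Itgb3 at log2 3.03. They included 4 of 17 erythroid genes (12 adjusted over the list alone, camera adjusted p = 5.0e-13), of which Hbb-bh1, Hbb-y and Hba-x are hemoglobins with reads uncertain between copies. The erythroid list stood at 1.47 in pro-HSC/HPC replicate 1, near the 1.49 of HE, and at 5.22 and 4.42 in replicates 2 and 3, so its rise lies in the latter. The megakaryocyte and platelet list stood at 2.62, 4.48 and 4.63 in replicates 1, 2 and 3 and at 1.94 in HE. edgeR called 100 genes, 77 higher and 23 lower. In each run that left out 1 library 10 of the 20 called genes from the size rule and the panel kept their call, as did 7 of 21 further called genes from the lists. The count was 218 with the replicate block, 201 with only these libraries in the fit, 20 without the libraries rich in hemoglobin reads (which leaves 1 pro-HSC/HPC library, assumed to vary like the other groups), 51, 54 and 50 without HE replicates 1, 2 and 3 in turn, and 66 without pro-HSC/HPC replicate 2.

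In pre-HSC I endothelial genes were lower and blood and ribosome biogenesis genes higher than in E10.5 HE. Prtn3, a protease of granule-bearing myeloid cells, rose by 7.85 ± 0.67 on the log2 scale, and Gfi1b by 6.49 ± 1.08. Tuba8, an alpha tubulin (chromosome 6, 121160788 to 121176115), had 1629 counts over the pre-HSC I libraries and 2 over HE, a depth-scaled ratio of 895 (95% counting interval 247 to 7399.8). Myb averaged 163 ± 44.5 CPM in pre-HSC I and 7.71 ± 5.03 in HE (log2 4.39 ± 0.74, edgeR adjusted p = 0.00042), Kit 244 ± 90.2 and 50.9 ± 13.6 CPM (log2 2.26 ± 0.37, edgeR adjusted p = 0.00031) and Runx1 225 ± 50.9 and 45.0 ± 6.61 CPM (log2 2.32 ± 0.35, edgeR adjusted p = 0.00015). The receptor Kdr, through which endothelium responds to VEGF, was lower in pre-HSC I (log2 -1.81 ± 0.27), as was Pmp22, a membrane protein of myelin (log2 -3.21 ± 0.66).

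Endothelial identity genes fell in 17 of 25 cases (23 adjusted over the list alone), with Icam2 at log2 -1.75 and the transcription factor Ets1 at -1.36 (camera adjusted p = 4.2e-26). Arterial genes fell in 13 of 20 (18 adjusted over the list alone, camera adjusted p = 2.5e-16), with Gja4 at log2 -2.21 and Notch1 at -1.43. Extracellular matrix and basement membrane genes fell in 12 of 26 (16 lower and 1 higher adjusted over the list alone, camera adjusted p = 4.4e-13), with Sparc at log2 -2.10. Of 27 pan-hematopoietic genes 13 rose (15 adjusted over the list alone), with the leukocyte GTPase Rac2 at log2 3.58 and Coro1a, an actin regulator of leukocytes, at 3.64 (camera adjusted p = 1.3e-17). Ribosome biogenesis and MYC genes rose in 16 of 26 (22 adjusted over the list alone, camera adjusted p = 2.0e-20), with Mycn at log2 2.63 and nucleolin, Ncl, at 1.03. S phase genes rose in 9 of 26 (19 adjusted over the list alone, camera adjusted p = 4.1e-12). Marker lists of other cells moved as well. The granulocyte and macrophage list ran from 0.877 to 0.927 in the HE libraries and 2.27 to 2.75 in those of pre-HSC I (camera adjusted p = 1.6e-09), and the megakaryocyte and platelet list from 1.99 to 2.75 in the HE libraries and 3.58 to 4.10 in those of pre-HSC I (camera adjusted p = 0.00087, and adjusted p = 0.1 with an estimated correlation). The cardiac list ran from 1.98 to 3.04 in the HE libraries and 1.30 to 1.77 in those of pre-HSC I (camera adjusted p = 0.0096, and adjusted p = 0.059 with an estimated correlation). The mesonephros and intermediate mesoderm list ran from 2.36 to 2.68 in the HE libraries and 1.83 to 2.12 in those of pre-HSC I (camera adjusted p = 0.095). edgeR called 1049 genes, 470 higher and 579 lower. Of the 25 called genes from the size rule and the panel, 18 kept their call in each run that left out 1 library, as did 43 of 72 further called genes from the lists. The count was 2327 with the replicate block and 656 without the libraries rich in hemoglobin reads. Those libraries are pro-HSC/HPC replicates 2 and 3 and pre-HSC I replicate 3, and only the last is part of this comparison. The count was 653 and 622 without HE replicates 2 and 3, and 512 without pre-HSC I replicate 2.

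Most genes that differed between the pre-HSC populations were lower in pre-HSC II. Cdh5 (chromosome 8, 106625525 to 106668402) averaged 77.2 ± 14.2 CPM in pre-HSC II and 328 ± 82.0 in pre-HSC I (log2 -2.09 ± 0.30, edgeR adjusted p = 2.4e-05). The arterial transcription factor Sox17 was also lower (log2 -4.62 ± 0.54, edgeR adjusted p = 1.4e-06). Tmem100 averaged 2.37 ± 1.29 and 106 ± 16.7 CPM (log2 -5.49 ± 0.67). The collagen gene Col3a1 (chromosome 1, 45368383 to 45406551) had 3 counts over pre-HSC II and 817 over pre-HSC I, a depth-scaled ratio of 302 (95% counting interval 103 to 1469) in favour of pre-HSC I. Higher in pre-HSC II was Rac2, with 256 ± 74.3 CPM against 54.8 ± 18.7 (log2 2.22 ± 0.36, edgeR adjusted p = 0.00012). Ptprc averaged 100.0 ± 34.4 and 11.4 ± 5.06 CPM (log2 3.13 ± 0.73, edgeR adjusted p = 0.0084), a call lost without pre-HSC I replicate 1 or pre-HSC II replicate 2 (adjusted p up to 0.078). Runx1 (log2 0.15 ± 0.34), Kit (log2 0.34 ± 0.35), Spn (log2 0.44 ± 0.97) and Hlf (log2 0.60 ± 0.75) did not pass the test.

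Endothelial identity genes fell in 21 of 25 cases (24 lower and 1 higher adjusted over the list alone), with Ramp2 at log2 -2.94 and the nitric oxide synthase Nos3 at -3.76 (camera adjusted p = 6.2e-54). Arterial genes fell in 19 of 20 (19 adjusted over the list alone), with Gja4 at log2 -4.68 and Jag1 at -3.96 (camera adjusted p = 1.8e-60). Extracellular matrix and basement membrane genes fell in 17 of 26 (22 adjusted over the list alone, camera adjusted p = 2.7e-46). TGF-beta and BMP pathway genes fell in 9 of 27 (15 adjusted over the list alone, camera adjusted p = 8.3e-12), with the inhibitor of differentiation Id3 at log2 -4.17. Notch pathway genes fell in 8 of 23 (10 adjusted over the list alone, camera adjusted p = 2.5e-10). Of 27 pan-hematopoietic genes 4 rose (4 adjusted over the list alone, camera adjusted p = 3.6e-08). Mesenchyme and smooth muscle genes stood at 2.74 in pre-HSC I and 1.30 in pre-HSC II. edgeR called 673 genes, 21 higher and 652 lower. At an unadjusted p under 0.05 340 were higher and 1459 lower. In each run that left out 1 library 16 of the 24 called genes from the size rule and the panel kept their call, as did 38 of 52 further called genes from the lists.

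**Figure D3:**
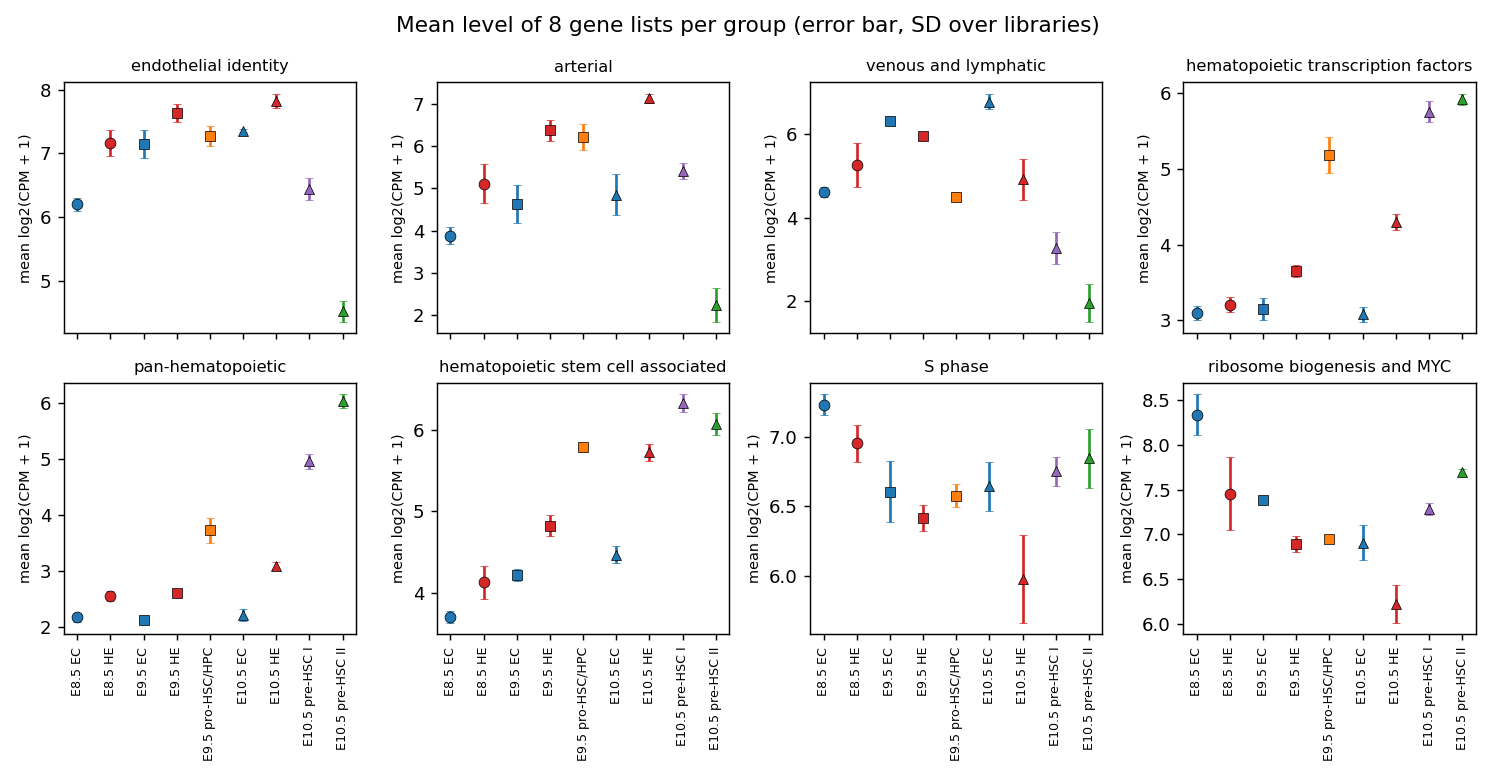
Mean log2(CPM + 1) of 8 gene lists on the vertical axes for the 9 populations on the horizontal axis, with each point the mean over a population's libraries and the error bar the SD. The arterial list stood at 4.85 in E10.5 EC and 7.13 in E10.5 HE.

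HE of successive days was compared to follow the same label through development, with the caution that the tissue label changes too between E9.5 and E10.5. In this and all other comparisons between days, any processing batch that goes with the day cannot be told apart from the day. Runx1 averaged 35.0 ± 3.67 CPM in E9.5 HE and 2.76 ± 1.16 in E8.5 HE (log2 3.66 ± 0.34, edgeR adjusted p = 7.9e-07), and Gfi1 2.71 ± 1.17 and 0.0576 ± 0.115 CPM (log2 5.33 ± 0.95, edgeR adjusted p = 0.0018). Akr1c14 had 0 counts in E8.5 HE and was at least 399-fold higher at E9.5, and the adhesion receptor Gpr126 rose by 6.81 ± 0.80 on the log2 scale. Phlda2, an imprinted growth regulator (chromosome 7, 150687453 to 150688429), had 0 counts in E9.5 HE and was at least 1108-fold lower than at E8.5, and the gut peptide Pyy at least 723-fold lower. In E8.5 HE replicate 3, however, Phlda2 stood at 0.0475 CPM against at least 39.7 in the other libraries, and Pyy at 1.38 CPM, the lowest of the 4 (highest 68.9). Arterial genes rose in 8 of 20 cases (12 adjusted over the list alone, camera adjusted p = 3.3e-08, and adjusted p = 0.13 with an estimated correlation). Stem cell genes rose in 3 of 22 and fell in 1 (9 and 1 adjusted over the list alone, camera adjusted p = 5.8e-05), with Angpt1 at log2 2.70. Glycolysis genes fell in 8 of 21 (13 adjusted over the list alone), with Pfkl at log2 -1.87 and Hk2 at -0.97 (camera adjusted p = 2.8e-07, and adjusted p = 0.054 with an estimated correlation). Some marker lists of other cells were higher in each E9.5 than in each E8.5 HE library. The neural and neural crest list ran from 0.104 to 0.985 at E8.5 and 1.41 to 1.70 at E9.5. The mesenchyme and smooth muscle list ran from 1.52 to 1.93 and 2.01 to 2.61, the cardiac list from 2.04 to 2.50 and 2.62 to 2.92, and the mast cell list from 0.496 to 0.858 and 1.24 to 1.62. The erythroid, lymphoid and endoderm lists overlapped. edgeR called 997 genes, 452 higher and 545 lower. Of the 17 called genes from the size rule and the panel, 11 kept their call in each run that left out 1 library, as did 28 of 67 further called genes from the lists. The count was 469 with only these libraries in the fit, 333 and 1529 without E8.5 HE replicates 1 and 3 in turn, and 334 and 264 without E9.5 HE replicates 1 and 3.

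From E9.5 to E10.5 HE had higher levels of stem cell genes and lower levels of glycolysis genes. Procr, the endothelial protein C receptor of stem cells, averaged 104 ± 19.6 CPM at E10.5 and 21.4 ± 5.67 at E9.5 (log2 2.28 ± 0.48, edgeR adjusted p = 0.0067), and Gata2 rose by 1.12 ± 0.21 on the log2 scale. The immediate early gene Fos (chromosome 12, 86814851 to 86818219) averaged 356 ± 242 and 18.4 ± 11.9 CPM (log2 4.28 ± 0.60, edgeR adjusted p = 0.0003). The Wnt receptor Fzd10 averaged 0.933 ± 1.04 CPM at E10.5 and 45.7 ± 22.1 at E9.5 (log2 -5.57 ± 1.14, edgeR adjusted p = 0.0057). Stem cell genes rose in 7 of 22 cases and fell in 1 (12 and 2 adjusted over the list alone), with the homeobox gene Meis1 at log2 1.45 (camera adjusted p = 1.5e-05). Interferon and inflammatory genes rose in 4 of 34 and fell in 1 (9 and 1 adjusted over the list alone), with Nfkbia at log2 1.66 (camera adjusted p = 8.0e-06). Glycolysis genes fell in 9 of 21 (14 adjusted over the list alone), with the hexokinase Hk2 at log2 -1.85 and the glucose transporter Slc2a1 at -1.56 (camera adjusted p = 2.7e-11). edgeR called 555 genes, 227 higher and 328 lower. In each run that left out 1 library 7 of the 15 called genes from the size rule and the panel kept their call, as did 21 of 51 further called genes from the lists. The count was 950 with only these libraries in the fit, 285, 321 and 210 without E9.5 HE replicates 1, 2 and 3 in turn, and 213 and 263 without E10.5 HE replicates 2 and 3.

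EC of E9.5 and E8.5 differed in more genes than any other pair compared, and a processing batch that goes with the day cannot be told apart from it here. Cdh5 averaged 518 ± 135 CPM at E9.5 and 105 ± 20.6 at E8.5 (log2 2.30 ± 0.30, edgeR adjusted p = 9.1e-06). Emcn, an endothelial sialomucin, averaged 602 ± 63.9 CPM at E9.5 (log2 4.16 ± 0.48, edgeR adjusted p = 1.4e-06). Trpc6, a calcium channel (chromosome 9, 8544142 to 8680741), had 0 counts in E8.5 EC and was at least 310.4-fold higher at E9.5. Phlda2 averaged 4.94 ± 3.61 CPM at E9.5 and 510.2 ± 293 at E8.5 (log2 -6.69 ± 1.23, edgeR adjusted p = 0.00056), and Itga2b changed by -2.19 ± 0.44 on the log2 scale. Genes of flow response and vascular tone rose in 11 of 16 cases (12 adjusted over the list alone), with Pde2a at log2 5.25 and thrombomodulin, Thbd, at 3.06 (camera adjusted p = 1.3e-10). Endothelial identity genes rose in 11 of 25 and fell in 1 (11 and 1 adjusted over the list alone), Egfl7 at log2 -1.71 being the one that fell (camera adjusted p = 0.00017, and adjusted p = 0.11 with an estimated correlation). Ribosome biogenesis and MYC genes fell in 16 of 26 and rose in 1 (21 and 1 adjusted over the list alone), with Myc at log2 -2.39 (camera adjusted p = 5.3e-10, and adjusted p = 0.11 with an estimated correlation). edgeR called 2999 genes, 1543 higher and 1456 lower. Of the 18 called genes from the size rule and the panel, 14 kept their call in each run that left out 1 library, as did 75 of 97 further called genes from the lists. The count was 1926 without E8.5 EC replicate 1 and 1979 and 1714 without E9.5 EC replicates 1 and 3.

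EC had higher levels of Fos and Sp110 at E10.5 than at E9.5, and no gene of the fixed panel was called. Fos averaged 257 ± 154 CPM at E10.5 and 25.2 ± 10.6 at E9.5 (log2 3.35 ± 0.57, edgeR adjusted p = 0.0057), and Sp110, a nuclear body protein of the interferon response, 10.8 ± 3.53 and 1.20 ± 0.766 CPM (log2 3.17 ± 0.56, edgeR adjusted p = 0.0066). Pcgf5, a polycomb ring finger gene (chromosome 19, 36453557 to 36530694), averaged 11.2 ± 0.346 CPM at E10.5 and 41.0 ± 7.22 at E9.5 (log2 -1.86 ± 0.26, edgeR adjusted p = 0.00048). Cholesterol biosynthesis genes were higher at E10.5 as a group (camera adjusted p = 2.2e-08), with Sqle at log2 0.90 and Cyp51 at 0.72, although edgeR called 0 of 19 over all genes and 10 adjusted over the list alone. Genes of flow response and vascular tone rose in 2 cases of 16 (3 adjusted over the list alone), Klf6 at log2 1.27 and the flow-induced factor Klf4 at 2.01 (camera adjusted p = 6.6e-05). Immediate early and heat shock genes ran from 3.67 to 4.31 in the E9.5 and 4.53 to 5.17 in the E10.5 libraries. Of these genes 2 of 20 rose (4 higher and 1 lower adjusted over the list alone), Fos and Zfp36 at log2 2.35 (camera adjusted p = 5.2e-05, and adjusted p = 0.063 with an estimated correlation). Marker lists of other cells parted the libraries as well. The lymphoid list ran from 2.15 to 2.35 at E9.5 and 3.05 to 3.11 at E10.5, and the mast cell list from 0.585 to 1.02 and 1.44 to 1.98. The cardiac list was lower at E10.5, with 1.95 to 2.92 at E9.5 and 1.11 to 1.73 at E10.5, as were the mesonephros and germ cell lists. edgeR called 116 genes, 47 higher and 69 lower. Beside these calls 1978 genes had an unadjusted p under 0.05, and DESeq2 called 418 and limma voom 954 genes. In each run that left out 1 library 4 of the 10 called genes from the size rule and the panel kept their call, as did 0 of 14 further called genes from the lists. The count was 37, 45 and 33 without E9.5 EC replicates 1, 2 and 3 in turn, and 26 and 36 without E10.5 EC replicates 2 and 3.

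Pre-HSC I of E10.5 had lower endothelial genes and higher leukocyte genes than pro-HSC/HPC of E9.5. Fmo1, a flavin monooxygenase, averaged 10.3 ± 8.98 CPM in pre-HSC I and 153 ± 19.2 in pro-HSC/HPC (log2 -3.89 ± 0.61, edgeR adjusted p = 0.00081), and Cyp26a1, an enzyme that degrades retinoic acid, 2.90 ± 1.29 and 41.3 ± 6.63 CPM (log2 -3.82 ± 0.69, edgeR adjusted p = 0.0029). Tespa1, a gene of lymphocyte signalling (chromosome 10, 129759908 to 129799698), rose by 6.60 ± 0.95 on the log2 scale. Runx1 (log2 -0.18 ± 0.34), Kit (log2 0.98 ± 0.35) and Gfi1 (log2 0.43 ± 0.73) did not pass the test. Endothelial identity genes fell in 5 of 25 cases (16 adjusted over the list alone), with Plvap at log2 -1.51 (camera adjusted p = 1.1e-13). Venous and lymphatic genes fell in 3 of 10 (6 adjusted over the list alone), with Nrp2 at -2.68 (camera adjusted p = 3.5e-08). Pan-hematopoietic genes rose in 4 of 27 (9 adjusted over the list alone), with Rac2 at log2 2.57 and Coro1a at 2.53 (camera adjusted p = 3.3e-14). The erythroid list stood at 2.11, 2.04 and 3.56 in pre-HSC I replicates 1, 2 and 3 and at 1.47, 5.22 and 4.42 in those of pro-HSC/HPC. Without the 3 libraries rich in hemoglobin reads it turned to a higher level in pre-HSC I, in a test with 1 pro-HSC/HPC library, assumed to vary like the other groups (camera adjusted p = 0.032). edgeR called 221 genes, 35 higher and 186 lower. Of the 11 called genes from the size rule and the panel, 5 kept their call in each run that left out 1 library, as did 5 of 28 further called genes from the lists. The count was 18 without the 3 libraries rich in hemoglobin reads, 91 and 92 without pro-HSC/HPC replicates 1 and 3 in turn, and 57 without pre-HSC I replicate 2.

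Whether the difference between HE and EC itself changed between days was tested as a difference of differences. Runx1 moved from no called difference at E8.5 to a higher level in HE at E9.5, a change of 3.76 ± 0.50 on the log2 scale (edgeR adjusted p = 0.00012), and Cd44 changed by 2.47 ± 0.41 (edgeR adjusted p = 0.0013). Genes of flow response and vascular tone had a smaller difference between HE and EC at E9.5 than at E8.5, with 3 of 16 called (4 adjusted over the list alone), including Cyp26b1, which degrades retinoic acid, at -5.63 and Pde2a at -4.54 (camera adjusted p = 2.8e-08). edgeR called 129 genes, 25 with a higher and 104 with a lower signed difference (HE over EC) at E9.5. A higher one can also mean a gene less far below EC. The count was 298 with the replicate block, 75 with only these libraries in the fit, and 84 and 83 without E9.5 HE replicates 1 and 2. Leaving out 1 library in turn kept 8 of the 9 called genes from the size rule and the panel and 10 of 18 further genes from the lists.

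Between E8.5 and E10.5 the difference between HE and EC changed by 4.78 ± 0.51 on the log2 scale for Runx1 (edgeR adjusted p = 2.6e-06), 3.34 ± 0.41 for Cd44 (edgeR adjusted p = 1.5e-05) and 1.74 ± 0.28 for Gata2 (edgeR adjusted p = 0.00038). Hematopoietic transcription factors had a higher signed difference at E10.5 in 4 of 22 cases (7 adjusted over the list alone, camera adjusted p = 1.5e-07). Venous and lymphatic genes had a lower one in 4 of 10 (8 adjusted over the list alone), with Aplnr at -3.69 and Flt4 at -1.75 (camera adjusted p = 2.0e-10). edgeR called 455 genes, 134 with a higher and 321 with a lower difference at E10.5. The count was 917 with the replicate block and 238 with only these libraries in the fit. When 1 library was left out in turn 9 of the 11 called genes from the size rule and the panel and 32 of 38 further genes from the lists kept their call.

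From E9.5 to E10.5 the difference between HE and EC changed in 2 genes by edgeR, both lower at E10.5. These were Oit3, a secreted protein of liver and endothelium (chromosome 10, 58885708 to 58904527), at -8.67 ± 1.49 (edgeR adjusted p = 0.04), a size that rests on few reads in E10.5 HE (0.0240 CPM), and Spry1 at -3.45 ± 0.61 (edgeR adjusted p = 0.04). Beside them stood 837 genes at an unadjusted p under 0.05, DESeq2 called 40 and limma voom 48 genes, and the replicate block gave 31. No call remained without E9.5 EC replicate 1 or 3, E9.5 HE replicate 2, E10.5 EC replicate 1 or E10.5 HE replicate 2 or 3, each run giving 0 genes, and 1 gene was called without E9.5 EC replicate 2. Venous and lymphatic genes were lower as a group in this test (camera adjusted p = 3.3e-07), with 2 of 10 called adjusted over the list alone.

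The step from HE to the blood population was compared between days in the same way, as pre-HSC I over HE at E10.5 against pro-HSC/HPC over HE at E9.5. Hk2, a hexokinase of glycolysis, changed by 2.54 ± 0.37 on the log2 scale (edgeR adjusted p = 0.002), Ptpn7, a phosphatase of blood cells, by 5.38 ± 0.77 (edgeR adjusted p = 0.002) and Samsn1, an adaptor of lymphocytes, by 3.52 ± 0.55 (edgeR adjusted p = 0.0041). Ribosome biogenesis and MYC genes had a larger step at E10.5 (camera adjusted p = 3.2e-20), with 18 of 26 called adjusted over the list alone. Endothelial identity genes had a lower one (camera adjusted p = 2.7e-14), with 8 of 25. edgeR called 11 genes, 5 with a higher and 6 with a lower step at E10.5. The count was 527 with the replicate block, 81 with only these libraries in the fit and 2 without the libraries rich in hemoglobin reads. Leaving out 1 library gave 4, 3 and 3 without E9.5 HE replicates 1, 2 and 3 in turn, and 3, 6 and 5 without pro-HSC/HPC replicates 1, 2 and 3. It gave 41, 5 and 6 without E10.5 HE replicates 1, 2 and 3, and 61, 3 and 4 without pre-HSC I replicates 1, 2 and 3. Of the 5 genes called by the size rule and the panel 3 kept their call in all these runs.

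Genes called in the same direction on several days were counted in comparisons that share no library. The comparisons do share 1 fit and its estimate of spread for each gene, and genes are not independent replicates. The counts for independent lists and the Fisher p-values are therefore descriptions only. Tmem100, Gja5, Itgb3, Vegfc and Nkx2-3 were among 23 genes higher in HE than EC at E8.5 and at E9.5, where independent lists would share 2.34 (Fisher's exact test, one-sided p = 3.4e-18). All 23 were also called at E10.5. E9.5 and E10.5 shared 42 genes against 0.969 (Fisher's exact test, one-sided p = 3.8e-67). E8.5 and E10.5 shared 96 higher genes against 16.3 (Fisher's exact test, one-sided p = 3.1e-48). They also shared 20 lower genes against 3.62 (Fisher's exact test, one-sided p = 6.3e-10), including Odc1, Gnl3 and Myc. In the opposite sense 24 genes higher at E8.5 were lower at E10.5 (10.6 expected) and 5 lower at E8.5 were higher at E10.5 (5.56 expected). Between E8.5 and E9.5 1 gene lower at E8.5 was higher at E9.5. In the step from HE to blood, pro-HSC/HPC and pre-HSC I shared 53 higher genes against 2.375, among them Runx1, Myb, Gfi1b, Ikzf1 and Ptprc (Fisher's exact test, one-sided p = 1.2e-62). The same steps shared 14 lower genes against 0.874, among them Flt4, Nr2f2 and Ets1 (Fisher's exact test, one-sided p = 6.7e-15). Both steps include libraries rich in hemoglobin reads, and Hbb-bh1 and Hbb-y are among the 53 higher genes. The overlap was not counted without those libraries.

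**Figure D4:**
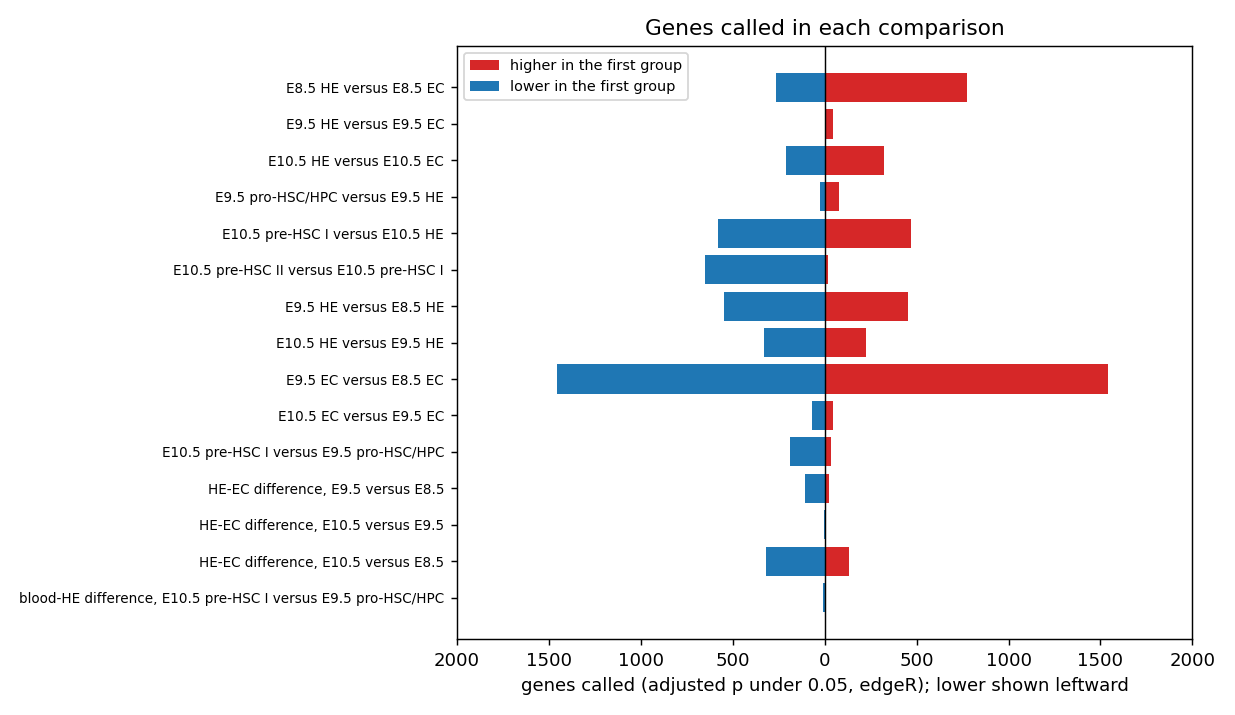
Number of genes called by edgeR in the 15 tests, with bars to the right of 0 for genes higher in the first group named and bars to the left for genes lower. The comparison of E9.5 EC with E8.5 EC had 1543 higher and 1456 lower genes, and that of pre-HSC II with pre-HSC I 21 higher and 652 lower.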

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

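The differences of differences were planned before the data were examined, as was the check for single libraries that stand apart within E8.5 HE, while the draws that shuffle both days were set apart only after the result was seen.

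The difference between HE and EC itself differed between days for several genes. Between E8.5 and E9.5 edgeR called 129 genes. Cd109, a membrane glycoprotein, changed by -7.70, from 8.75 at E8.5 to 1.05 at E9.5 on the log2 scale, and Trpc6, a calcium channel, by -9.98. Atxn1, an RNA-binding protein, changed by -6.01, Clu, a secreted chaperone, by -3.405 and Sema6d, a semaphorin, by -3.93. Between E8.5 and E10.5 edgeR called 455 genes, and the difference changed by 4.78 for Runx1, -7.95 for Cd109, -11.50 for Trpc6, -5.50 for Clec1b, a platelet receptor, and -4.43 for Igf1, a growth factor. Between E9.5 and E10.5 edgeR called 2 genes, Oit3 at -8.67 and Spry1 at -3.45. The step from HE to blood differed between days in 11 genes, among them Ptpn7 at 5.38, Hk2 at 2.54, Samsn1 at 3.52, Serpina3g, a serpin, at -7.93 and Anxa6, an annexin, at -1.505. Trpc6 had 0 counts in E8.5 EC and Serpina3g 0 in E9.5 HE, so the sizes of their changes are set by the fit and not measured. Atxn1 in E8.5 EC (0.0537 CPM) and Oit3 in E10.5 HE (0.0240 CPM) rest on few reads.

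Other ways of drawing the libraries were counted, 25 for each of these tests with only the libraries concerned in the fit. For E9.5 against E8.5 1 of 25 draws, the real one, called as many as its 75 genes, and the highest other called 1. For E10.5 against E9.5 4 of 25 called as many as 2 (highest other 199), and draws that shuffled both days reached 6, so that chance is not excluded there. For E10.5 against E8.5 2 of 25 called as many as 238 (highest other 266), and for the step from HE to blood 2 of 25 as many as 81 (highest other 408). In the latter 2 tests the other draw as high kept 1 day's grouping or its mirror and so carried that day's difference, which points to a structure of the samples, and its count does not speak for chance. The draws that shuffled both days called at most 0 genes for E9.5 against E8.5 (21 draws), 1 for E10.5 against E8.5 (23 draws) and 1 for the step (21 draws). They remove the differences of both days at once and do not keep the pairs, so for these 3 tests it is left open whether chance is excluded for the change between days.

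Of 81 values checked in the 4 E8.5 HE libraries 11 had 1 library apart from the rest. In 7 of them the other libraries are at 0, where any read sets 1 library apart. Of the 74 remaining values 4 had 1 library apart, where chance gives about 5 in 100. Runx1 was 1.03 CPM in replicate 4 (3.14 to 3.46 in the others), Kdr 214 CPM in replicate 1 (303 to 320.4), and Cyp26b1 35.6 CPM in replicate 3 (12.8 to 16.0). Ikzf1 was 1.70 CPM and Ptprc 0.134 CPM in replicate 4, Gfi1b 0.808 and Gpr126 1.33 CPM in replicate 3, Gfi1 0.230 and Prl3b1 0.845 CPM in replicate 2, and Anxa1 0.0448 CPM in replicate 4, each with 0 in the other libraries. The mast cell list stood at 0.496 in replicate 2 and at 0.799 to 0.858 in the others. The check takes each value alone and cannot show a library shifted as a whole. On the second principal component replicate 3 stood at -15.5 and the others at 17.6 to 43.4, while E9.5 HE stood at -61.4 to -47.1. Leaving out replicate 3 moved E8.5 HE against EC from 1038 to 582 calls and E9.5 against E8.5 HE from 997 to 1529.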

How the results depend on the processing

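The run without the libraries rich in hemoglobin reads was chosen only after the data were seen, and all other alternatives were planned. Counts of called genes that moved by more than 1.5 times are given here, and the cause was not tested for any of them.

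With DESeq2 the counts were 1698 in E8.5 HE against EC, 169 in E9.5 HE against EC, 945 in E10.5 HE against EC, 218 in pro-HSC/HPC against HE, 1587 in pre-HSC I against HE, 1735 in E9.5 against E8.5 HE, 1055 in E10.5 against E9.5 HE, 418 in E10.5 against E9.5 EC, 490 in pre-HSC I against pro-HSC/HPC, 293 in the HE-EC difference E9.5 against E8.5, 40 in the HE-EC difference E10.5 against E9.5, 794 in the HE-EC difference E10.5 against E8.5 and 193 in the blood-HE difference. With limma voom they were 1759 in E8.5 HE against EC, 287 in E9.5 HE against EC, 1194 in E10.5 HE against EC, 398 in pro-HSC/HPC against HE, 2180 in pre-HSC I against HE, 1945 in E9.5 against E8.5 HE, 1606 in E10.5 against E9.5 HE, 5559 in E9.5 against E8.5 EC, 954 in E10.5 against E9.5 EC, 1039 in pre-HSC I against pro-HSC/HPC, 289 in the HE-EC difference E9.5 against E8.5, 48 in the HE-EC difference E10.5 against E9.5, 788 in the HE-EC difference E10.5 against E8.5 and 511 in the blood-HE difference. Without a filter they were 100 in E9.5 HE against EC, 155 in pro-HSC/HPC against HE, 10 in the HE-EC difference E10.5 against E9.5 and 30 in the blood-HE difference, and with the stricter filter 70 in E9.5 HE against EC, 184 in E10.5 against E9.5 EC and 47 in the blood-HE difference. With only the groups compared in the fit they were 191 in E8.5 HE against EC, 140 in E9.5 HE against EC, 201 in pro-HSC/HPC against HE, 469 in E9.5 against E8.5 HE, 950 in E10.5 against E9.5 HE, 75 in the HE-EC difference E9.5 against E8.5, 238 in the HE-EC difference E10.5 against E8.5 and 81 in the blood-HE difference. With the replicate block they were 2193 in E8.5 HE against EC, 168 in E9.5 HE against EC, 1316 in E10.5 HE against EC, 218 in pro-HSC/HPC against HE, 2327 in pre-HSC I against HE, 298 in the HE-EC difference E9.5 against E8.5, 31 in the HE-EC difference E10.5 against E9.5, 917 in the HE-EC difference E10.5 against E8.5 and 527 in the blood-HE difference, and no other count moved as far. In pre-HSC II against I same-numbered libraries correlated at 0.510 in pair 1 and 0.454 in pair 3. Pair 2, at 0.0618, missed the bound of 0.1, so the numbers were not taken as pairs there, and the block gave 938. Between days the median correlation of same-numbered libraries was -0.0174 or lower, and the numbers were not taken as pairs either. Without the libraries rich in hemoglobin reads the counts were 20 in pro-HSC/HPC against HE, 656 in pre-HSC I against HE, 18 in pre-HSC I against pro-HSC/HPC and 2 in the blood-HE difference.

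With DESeq2 calls E8.5 and E9.5 shared 78 genes higher and 3 lower in HE than EC, E8.5 and E10.5 178 and 59, E9.5 and E10.5 125 and 4, and the blood steps 81 and 46. With a fold minimum of 2 E8.5 and E10.5 shared 8 lower genes, since fewer genes pass. Leaving out 1 library at a time gave 582 to 1373 in E8.5 HE against EC, 1714 to 2920 in E9.5 against E8.5 EC, 83 to 182 in the HE-EC difference E9.5 against E8.5, 318 to 525 in the HE-EC difference E10.5 against E8.5, 264 to 1529 in E9.5 against E8.5 HE, 11 to 38 in E9.5 HE against EC, 26 to 114 in E10.5 against E9.5 EC, 0 to 3 in the HE-EC difference E10.5 against E9.5, 50 to 85 in pro-HSC/HPC against HE, 210 to 489 in E10.5 against E9.5 HE, 3 to 61 in the blood-HE difference, 57 to 181 in pre-HSC I against pro-HSC/HPC, 284 to 455 in E10.5 HE against EC, 512 to 1091 in pre-HSC I against HE and 468 to 622 in pre-HSC II against I.

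Without the libraries rich in hemoglobin reads the log2 difference of Hbb-bh1 between pro-HSC/HPC and HE turned to -2.04 and that of Hba-x to -2.34. The erythroid and megakaryocyte lists turned direction between pre-HSC I and pro-HSC/HPC (camera adjusted p = 0.032 and 0.023) and in the blood-HE difference (adjusted p = 0.34 and 0.74). Without E9.5 EC replicate 3 the mesenchyme list turned in E9.5 HE against EC (adjusted p = 0.023, and 0.023 to 0.67 over the runs that left out 1 library). Cytosolic ribosomal proteins, whose reads are uncertain between copies, turned without E10.5 EC replicate 1 in the HE-EC difference E10.5 against E9.5 (adjusted p = 0.00022, range 0.00022 to 0.97) and without pre-HSC I replicate 1 in pre-HSC I against HE (adjusted p = 0.95, range 1.2e-07 to 0.95) and the blood-HE difference (adjusted p = 0.76, range 8.4e-07 to 0.76). Of 813 called named genes 802 kept their call with DESeq2 size factors, 797 with upper-quartile factors and 789 with the block, and DESeq2 kept 800 of 809. With only the groups compared 637 of 799 kept it, without the libraries rich in hemoglobin reads 151 of 258 (105 lost, 2 reversed), and over all runs that left out 1 library 4420 of 5622. Of 226 list calls 217 held with the block and 168 with fry, and 1476 of 1674 over the runs that left out 1 library. Other scalings moved the median of all genes by at most 0.0596 on the log2 scale. In the blood-HE difference other scalings gave 62.5% higher calls against 45.5%. Marker levels moved by more than 1 SD in 94 of 108 cases with a higher pseudocount and 88 with a lower one, so they compare only at 1 pseudocount. At 16308918 to 31405603 counts a library and 3 or 4 libraries a population, most changes of 2-fold were missed in the simulated data. Those data are simpler than the real ones, as given above.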

Other observations

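Tests chosen only after the result was seen are those of a lower endothelial share in E8.5 EC and of posterior Hox genes, and the runs without the libraries rich in hemoglobin reads.

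Signalling and matrix genes also differed between E10.5 HE and EC. Extracellular matrix and basement membrane genes rose in 5 of 26 cases and fell in 1 (9 and 1 adjusted over the list alone), with fibronectin, Fn1, at log2 2.39 and fibrillin, Fbn1, at 3.13 (camera adjusted p = 6.8e-07). Notch pathway genes rose in 5 of 23 (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 6.1e-06), with the effector Hey2 at log2 4.06. TGF-beta and BMP pathway genes rose in 6 of 27 and fell in 1 (10 and 2 adjusted over the list alone), with the inhibitory Smad7 at log2 2.47 and the ligand Bmp4 at -3.40 (camera adjusted p = 0.00073, and adjusted p = 0.057 with an estimated correlation). Glycolysis genes fell in 3 of 21 (10 adjusted over the list alone, camera adjusted p = 1.7e-05), with the phosphofructokinase Pfkp at log2 -1.64. Some marker lists of other cell types were higher in HE as well. The mesonephros and intermediate mesoderm list stood at 2.36 to 2.68 in the HE and 1.37 to 1.66 in the EC libraries (camera adjusted p = 0.0025). The mesenchyme and smooth muscle list stood at 2.42 to 4.37 in HE, the highest in replicate 1, and 1.58 to 3.61 in EC (camera adjusted p = 0.0097, and adjusted p = 0.38 with an estimated correlation). Whether cells of other types carry the matrix and signalling changes was not tested.

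Immediate early and heat shock genes were higher in E10.5 than in E9.5 HE, 4 of 20 higher and 1 lower (6 and 1 adjusted over the list alone), with Egr1 at log2 2.91 and Zfp36 at 2.94 (camera adjusted p = 3.0e-05, and adjusted p = 0.067 with an estimated correlation).
Between E8.5 and E9.5 HE, S phase genes fell in 10 of 26 cases (13 lower and 1 higher adjusted over the list alone), with the endonuclease Fen1 at log2 -1.43 and the histone mRNA binding Slbp at -1.28 (camera adjusted p = 9.8e-08, and adjusted p = 0.13 with an estimated correlation).

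The E8.5 EC libraries stood apart with low levels of many endothelial genes. A lower share of endothelial cells would shift the endothelial identity genes by 1 shared amount. This holds only if the other cells express none of these genes and EC and HE are otherwise alike. The differences between HE and EC scattered more than their standard errors allow (chi-square of 7.73 per degree of freedom about 1 shared difference). These standard errors were derived from the log2 difference and the quasi-likelihood test statistic, and genes are not independent replicates. Egfl7, Kdr and Ramp2 were not higher in HE. These values argue against a lower share alone under those conditions. They cannot exclude a lower share beside other differences between the populations. Replicate 3 alone is argued against, since 2920 genes were still called between E9.5 and E8.5 EC without it. The other scalings left 3007 or more genes called, but they shifted this comparison by only 0.00254 and 0.0483 on the log2 scale. They lie too near the TMM scaling to decide whether the scaling plays a part. A larger posterior part of the dissection in EC than in HE stays open as a hypothesis, since Hox genes of groups 9 and above were lower in HE relative to those of groups up to 4 by a mean log2 of -2.24 (11 and 12 genes, permutation p = 0.0141 from 100000 resamples, over genes, which are not independent replicates). The whole Hox list was lower in HE than in EC at E8.5 (1.94 and 2.43) and also at E9.5 (1.97 and 2.38). Endothelial identity genes nevertheless averaged 7.14 in E9.5 EC, against 6.20 in E8.5 EC. A lower Hox level in HE is thus not particular to E8.5 and need not go with low endothelial genes in EC. Biological differences between the sorted populations were not tested.

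Far more genes were lower than higher in pre-HSC II compared with pre-HSC I. Under the other scalings at most 3.44% of calls were higher. Those scalings shifted the comparison by only -0.00539 and 0.0129 on the log2 scale, too little to decide whether the scaling plays a part. If pre-HSC I held only pre-HSC II cells and HE cells, all genes would lie at 1 position between pre-HSC II (0) and HE (1). Genes higher in pre-HSC II lay at 0.548 on average (0.479 to 0.618 over the libraries, 189 genes). Genes higher in HE lay at 0.235 to 0.286 (562 genes). These values argue against such a mixture alone. They cannot exclude HE cells mixed into a pre-HSC I population that has its own profile. A biological difference between the stages stays open and was not tested further.

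Hemoglobin reads were high in pro-HSC/HPC replicates 2 and 3 and pre-HSC I replicate 3. For 1 outside source of erythroid RNA, other erythroid transcripts should keep 1 ratio to hemoglobin, with a bound of 4 set beforehand, and the largest ratio was 4.03 times the smallest. By that bound the value argues against this source, but the test was set aside after the value was seen, because Car2, which is on the list, reached 28.4 to 567 CPM in blood libraries poor in hemoglobin, so it decides nothing.

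Other splits of the same libraries were counted for each comparison with only its libraries in the fit. At E8.5, HE against EC called 191 genes, and 2 of 35 splits called as many, the highest other 204, so chance is not excluded. That other split set EC replicates 1 and 2 with HE replicates 1 and 2, which follows the replicate numbers, while the 7 splits that part all pairs called at most 0. For E9.5 against E8.5 HE, 2 of 35 called as many as 469, and the highest other, with E8.5 HE replicate 3 placed among the E9.5 libraries, called 720. In the 3 against 3 designs there are 10 splits, too few for a share under 0.05, and 1, the real one, gave the most. The real and highest other counts were 140 and 0 for E9.5 HE against EC, 520 and 0 for E10.5 HE against EC, 201 and 0 for pro-HSC/HPC against HE, 993 and 0 for pre-HSC I against HE, 550 and 0 for pre-HSC II against pre-HSC I, 950 and 0 for E10.5 against E9.5 HE, 2626 and 0 for E9.5 against E8.5 EC, 167 and 0 for E10.5 against E9.5 EC, and 236 and 4 for pre-HSC I against pro-HSC/HPC.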
